A study of Mus musculus with 6 samples.

How the data were processed

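RNA from the distal jejunum of 6 mice was hybridised to Affymetrix expression arrays, 1 array per animal, per the labels and the design text. Of these mice, 3 were controls and 3 were mutant littermates in which Hnf4a had been deleted in the intestinal epithelium with a Villin-Cre transgene, and all were killed at 7 months of age. The labels describe the tissue as biopsies of total jejunum, so RNA of muscle, stroma and immune cells was measured together with that of the epithelium. The values used here are the authors' deposited log2 signals, 1 per probe set and array. The background correction, the summarisation and the normalisation behind them are not given in the sources used here. The log2 scale was read from the values, which ran from 1.80 to 14.5. Array medians lay between 3.93 and 3.98, within the limit of 0.1 set beforehand, so the values were used as deposited with no further normalisation.

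The table held 45101 probe sets. After 64 Affymetrix control probe sets were left out, 45037 remained. The platform annotation paired 34945 of them with 1 gene symbol, 932 with several and 9160 with none listed. Entrez identifiers of 34754 of the probe sets with 1 symbol were found in the RefSeq table of assembly GRCm38.p6, which was used for names only, and 0 symbols needed updating. The series names no genome build, so no coordinates are given. Each gene was represented by its brightest probe set with 1 symbol, taken as the highest mean over the 6 arrays. This left 18193 genes, of which 9010 had more than 1 probe set. No gene was named from a probe set with several symbols.

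Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with group as the only term, two-sided tests and Benjamini-Hochberg adjustment over all 18193 genes. A gene was called changed at an adjusted p under 0.05. Fold differences, standard errors (SE) and 95% intervals come from this fit. Each p-value rests on the spread between individual animals, which eBayes draws toward the spread common to all genes. The number of arrays limits the precision. On simulated data of 3 control and 3 mutant arrays with 18193 genes, of which 200 were changed and all were drawn independently, the procedure recovered 19.4% of the genes changed by 0.5 on the log2 scale, 71.6% of those changed by 1 and 97.0% of those changed by 2. False calls made up 3.1% of the calls, and 0 genes were called when none had been changed.

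Lists of genes, 36 in number, were fixed before the data were examined. They covered brush border digestive enzymes with a few structural proteins of the brush border, nutrient transporters, apolipoproteins and dietary lipid handling, fatty acid oxidation with ketogenesis and peroxisome, cholesterol synthesis, bile acid uptake and FXR targets, antioxidant and glutathione enzymes, oxidases that produce reactive oxygen species (ROS), drug and xenobiotic metabolism, oxidative phosphorylation, Wnt targets and stem cell markers, proliferation, p53 targets and cell death, the unfolded protein response, tight junction and adhesion, intestinal transcription factors, the antimicrobial and inflammatory epithelial response, the interferon response with MHC class II, the circadian clock, and Y-linked genes with Xist. Marker lists covered goblet, Paneth, enteroendocrine and tuft cells, T cells with intraepithelial lymphocytes, B and plasma cells, macrophages and other myeloid cells, smooth muscle, fibroblasts and matrix, endothelium, enteric neurons and glia, pancreatic acinar cells, fat, red blood cells, the duodenum or proximal end, and the ileum or colon. Of the 726 genes on the lists, 654 were measured, and the others were not analysed here. Lists with at least 5 measured members, 34 in all, were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists. Camera compares a list with all other genes. For each list the number of members past the test is given over all genes and adjusted over the list alone.

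The genes named were chosen by a rule written before the data were examined. It took Hnf4a, the 12 genes with the largest rise and the 12 with the largest fall among the changed genes whose mutant values all lay beyond all control values and whose higher group mean exceeded the median gene, and up to 4 members of each list with the smallest p. Any gene named outside this rule is said to have been chosen after its values were seen.

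The alternatives planned beforehand were quantile normalisation, centring of each array on its median, a floor at the 20th percentile, a filter on dim probe sets, other rules for choosing probe sets, a variance model with trend and robust fitting, array weights (statmod 1.5.0 was installed), a test with no moderation of the variance, the replicate number as a block, stricter thresholds, other set tests (camera with an estimated correlation, and fry) and the omission of each array in turn. After the data were seen, 2 more were added, namely Y-linked expression as a covariate and the joint omission of control 3 and mutant 2.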

Results

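Gene expression was measured in the distal jejunum of 3 control mice and 3 littermates that lacked Hnf4a in the intestinal epithelium, at 7 months of age. Hnf4a encodes a nuclear receptor that regulates epithelial and metabolic genes in liver, gut and kidney. The series title frames the work around gut neoplasia and reactive oxygen species, and its design holds 1 comparison, mutant against control. Each animal had its own array. Rank correlations between arrays ranged from 0.980 to 0.987 over all probe sets, and no pair of arrays was a duplicate. The difference between the 3' and the 5' probe set of actin, a sign of RNA integrity, lay between 0.39 and 0.66 (log2) in controls and between 0.42 and 0.73 in mutants. The same difference for Gapdh lay between 0.38 and 0.48 in controls and was 0.71, 0.29 and 0.58 in mutants 1, 2 and 3.

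Hnf4a itself fell in the mutants. Its log2 signal was 11.72 ± 0.13 (SD, n = 3) in controls and 9.16 ± 0.57 (SD, n = 3) in mutants, which was 5.88-fold lower (limma's moderated test, adjusted p = 0.00756). The other Hnf4a probe sets differed by -3.06, -2.64 and -1.17 on the log2 scale, and the last of these did not pass the test over all probe sets (adjusted p = 0.0921). In mutant 3 the brightest probe set read 9.82, above the 8.83 of both other mutants. Where these probe sets lie relative to the deleted exons is not given in the sources used here, so a remaining signal does not measure how complete the deletion was. Without control 2, Hnf4a missed the threshold (log2 change -2.53, adjusted p = 0.0506).

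**Figure D1:**
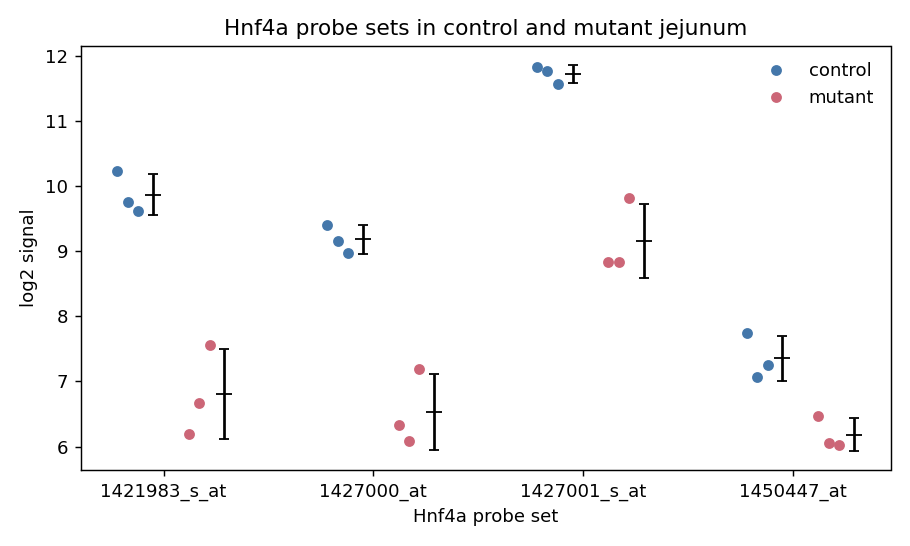
Log2 signal (vertical axis) of the 4 Hnf4a probe sets (horizontal axis) in each of the 3 control arrays (blue) and 3 mutant arrays (red), with the group mean and SD in black. In every probe set the 3 mutant arrays lie below the 3 control arrays, with mean differences from -3.06 to -1.17.

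The largest falls after deletion of Hnf4a were in Cyp2b10, Aadac and Pm20d1. Cyp2b10, a cytochrome P450 of drug metabolism, fell 26.6-fold (log2 change -4.73 ± 0.14 SE, adjusted p = 4.94e-06), the esterase gene Aadac 20.2-fold (log2 change -4.33 ± 0.32 SE), and Pm20d1, which encodes an enzyme that makes N-acyl amino acids, 17.1-fold (log2 change -4.10 ± 0.12 SE). The mutant values of Pm20d1 lay below the median probe set of each array, where signal is close to background, so the size of its fold is uncertain. Rdh7, of the retinol dehydrogenase family, fell 7.77-fold, Fbp1, an enzyme of gluconeogenesis, 5.23-fold, and Car4, a membrane-bound carbonic anhydrase, 5.09-fold. Also lower were the prostaglandin reductase gene Ptgr1 at 4.90-fold, the aldo-keto reductase genes Akr1c14 and Akr1c19 at 4.54-fold and 4.33-fold, the imino acid transporter gene Slc6a20a at 3.87-fold, and Nr1i3 at 3.83-fold. Nr1i3 encodes the nuclear receptor CAR, which controls Cyp2b10 in liver. With 1 array left out, the call was lost for Ptgr1 (without control 3 or mutant 2), Slc6a20a (control 2, control 3 or mutant 2), Nr1i3 (any but control 1 or mutant 2) and Akr1c19 (any but mutant 3), with adjusted p up to 0.0688, 0.0981, 0.0851 and 0.166.

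Retnlb showed the largest rise. It encodes a goblet cell peptide with antimicrobial action, and rose 43.0-fold from a log2 signal of 3.36 ± 0.37 (SD, n = 3) to 8.79 ± 1.03 (SD, n = 3), with a log2 change of 5.43 ± 0.45 SE (adjusted p = 0.00533). Its control values likewise lay below the median probe set of each array, so the size of its fold is uncertain too. Onecut2, Slc22a4 and Sval1, named below, had a lower group with at least 2 of 3 values under that median, and the same limit holds for them. Onecut2 also read under it in controls 1 and 2, at 3.73 and 3.78, so whether it was expressed at all is uncertain. The next rises among genes whose higher group mean exceeded the median gene were 4.76-fold for ccdc198, 3.52-fold for Sval1, 3.44-fold for the complement gene C2 and 3.15-fold for S100g, which encodes the vitamin D-dependent calcium binder calbindin-D9k. Car8 rose 2.97-fold, the metallothionein gene Mt1 2.76-fold, the sialyltransferase gene St8sia6 2.70-fold and the secreted phospholipase gene Pla2g10 2.42-fold. Myl7, a myosin light chain gene of cardiac atrium, rose 2.38-fold, and the uncharacterised transcripts BC064078 and 2210407C18Rik rose 2.61-fold and 2.34-fold. Adjusted p of these 12 genes lay between 0.00533 and 0.0319, and that of the 12 genes with the largest falls between 4.94e-06 and 0.0351. Among the rises, Retnlb, Car8 and Pla2g10 passed with any 1 array left out. Lost calls were C2 and BC064078 (without control 2, control 3 or mutant 2, adjusted p up to 0.0809 and 0.127), ccdc198 (any control or mutant 2, up to 0.127), S100g (control 1, control 2, mutant 2 or mutant 3, up to 0.134), St8sia6 and Sval1 (control 1, control 3, mutant 2 or mutant 3, up to 0.127 and 0.152), Mt1 and 2210407C18Rik (any but mutant 1, up to 0.105 and 0.127) and Myl7 (any but mutant 3, up to 0.133). The mean of a gene's probe sets also ended the calls of Mt1 (adjusted p = 0.0943) and BC064078 (adjusted p = 0.0618).

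**Figure D2:**
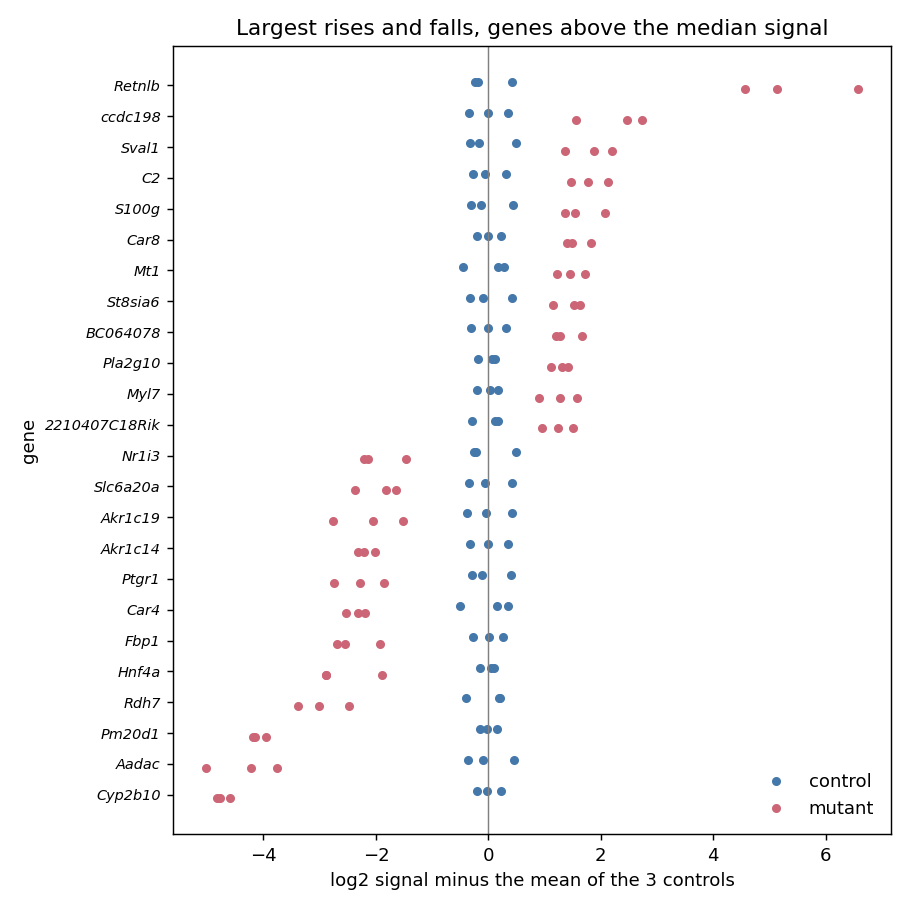
Log2 signal of each array minus the mean of the 3 controls (horizontal axis) for 24 genes (vertical axis), the 12 largest rises and the 12 largest falls among changed genes whose higher group mean exceeded the median gene, with 3 control arrays in blue and 3 mutant arrays in red. Mean changes run from -4.73 for Cyp2b10 to 5.43 for Retnlb, and in each gene the mutant arrays lie beyond all control arrays.

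In total, 96 of 18193 genes changed, 36 of them higher and 60 lower, and 65 changed at least 2-fold. At an unadjusted p under 0.05 there were 2200 genes, 954 higher and 1246 lower. The 3 mutants lay wholly beyond the 3 controls in 17.1% of genes, where chance gives 10%. They also did so in all 96 changed genes, but a gene with overlapping groups could hardly have been called. For 40 of the changed genes a further 63 probe sets were on the array, and 57 of these moved the same way, 42 with an unadjusted p under 0.05, while 0 moved the other way at that level in limma's test. The count of changed genes depended on which array was left out. It was 76, 24 and 22 without controls 1, 2 and 3, and 96, 41 and 71 without mutants 1, 2 and 3. Fewer arrays also give less power. Of the 96 genes of the main fit, 16 passed with any 1 array left out, and 80 lost the call without at least 1 array. For 65 the call was lost for at least 3 of the arrays. In each of these refits all 96 kept their direction and an unadjusted p under 0.05 in limma's test, though they were chosen on the same arrays.

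Some arrays carried transcripts of other tissue or cell types. Control 3 held pancreatic acinar transcripts, with a log2 signal of 8.95 for Cela2a, 8.18 for Cpb1 and 7.12 for Cpa1, against at most 2.93, 3.76 and 3.83 in the other arrays. Mutant 2 held fat transcripts, with 10.4 for Adipoq and 11.4 for Fabp4 against at most 8.21 and 9.31 elsewhere. These genes were picked after their values were seen. Y-linked transcripts were present in control 1 and mutant 3, so 1 animal in each group was male, and none of the 4 measured genes of that list passed the test (median log2 change -0.22, 0 past adjusted over the list alone, too few for the set test). Without control 3 and mutant 2 together 4 genes changed, namely Cyp2b10, Nr1i3, Pm20d1 and Retnlb.

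Drug and xenobiotic metabolism was the lowest-lying metabolic list. Of its 32 measured genes, 2 fell (Cyp2b10 and Abcc2), 0 rose and 30 did not pass, and adjusted over the list alone 19 fell and 3 rose. Abcc2, which encodes the canalicular export pump MRP2, fell by 1.20 ± 0.18 SE (adjusted p = 0.0319, up to 0.156 and lost without control 2, control 3, mutant 2 or mutant 3), whereas the carboxylesterase gene Ces2a differed by 0.66 the other way (adjusted p = 0.0521). The list median was -0.42 (camera adjusted p = 1.75e-08, and adjusted p = 0.369 with an estimated correlation).

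Nutrient transporters fell in part. Of 24 measured genes, 4 fell, 0 rose and 20 did not pass, and adjusted over the list alone 11 fell and 1 rose. The imino acid transporter gene Slc6a20a fell by 1.95 ± 0.24 SE, Slc6a19, the main apical carrier of neutral amino acids, by 1.10 ± 0.13 SE, the biotin and pantothenate carrier gene Slc5a6 by 1.31 ± 0.19 SE and the ergothioneine carrier gene Slc22a4 by 1.10 ± 0.18 SE. The Slc22a4 call was lost when any array but mutant 2 was left out (adjusted p up to 0.233), under quantile normalisation (adjusted p = 0.0625) and median centring (adjusted p = 0.0574), and with the mean of a gene's probe sets (adjusted p = 0.0513). That of Slc5a6 was lost without any control or mutant 2 (adjusted p up to 0.17), and that of Slc6a19 without control 2 or control 3 (adjusted p up to 0.0981) and with the mean of its probe sets (adjusted p = 0.0533). The list median was -0.32 (camera adjusted p = 6.83e-08, and adjusted p = 0.369 with an estimated correlation). Among 19 measured brush border genes, most of them digestive enzymes, none passed over all genes, and adjusted over the list alone 5 fell and 0 rose. The peptidase genes Xpnpep2 and Ace differed by -0.93 ± 0.24 SE and -0.95 ± 0.28 SE and the protocadherin gene Cdhr2 by -0.44 ± 0.12 SE, and the median was -0.30, or -0.18 without mutant 3 (camera adjusted p = 1.98e-05, and adjusted p = 0.369 with an estimated correlation).

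Lipid handling lay lower in the mutants without any single gene past the test. For apolipoproteins and dietary lipid handling, 0 of 26 measured genes passed, and adjusted over the list alone 4 fell and 0 rose. Fabp1, the liver-type fatty acid binding protein gene, differed by -1.23 ± 0.24 SE (adjusted p = 0.0798), the cholesterol exporter gene Abca1 by -1.02 ± 0.22 SE and Dgat1 by -0.44 ± 0.09 SE. The median was -0.13, or -0.19 without control 2 and -0.20 without mutant 2 (camera adjusted p = 3.83e-05, and adjusted p = 0.393 with an estimated correlation). For fatty acid oxidation, ketogenesis and peroxisome, 0 of 22 genes passed, with 1 lower adjusted over the list alone, Hsd17b4 at -0.69 ± 0.14 SE. Its median was -0.19, or -0.12 without control 1 (camera adjusted p = 0.0123, and adjusted p = 0.568 with an estimated correlation), and without mutant 3 the call was lost (median -0.08, adjusted p = 0.268). Cholesterol synthesis had 0 of 18 genes past the test and 0 adjusted over the list alone, a median of 0.24 and a camera adjusted p of 0.0517 (adjusted p = 0.628 with an estimated correlation). That list passed camera without control 1 (adjusted p = 0.0405), control 3 (adjusted p = 0.0112), mutant 1 (median 0.38, adjusted p = 0.00818) or mutant 2 (adjusted p = 0.0046), while its median was 0.06 without control 2 and -0.09 without mutant 3. It also passed with trend and robust fitting (adjusted p = 0.0494), the replicate block (adjusted p = 0.00981), the Y-linked covariate (adjusted p = 0.0134) and without control 3 and mutant 2 together (median 0.42, adjusted p = 0.000586).

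Antioxidant and glutathione enzymes bear on the series title. Of 34 measured genes, 1 fell, 0 rose and 33 did not pass, and adjusted over the list alone 7 fell and 0 rose. The gene that fell was Gsta4, a glutathione transferase acting on lipid peroxidation products, at 2.10-fold (log2 change -1.07 ± 0.16 SE, adjusted p = 0.0378). Its call was lost when any array but mutant 3 was left out (adjusted p up to 0.16) and under quantile normalisation (adjusted p = 0.0509). Gclm, a subunit of the enzyme that starts glutathione synthesis, differed by -0.70 ± 0.14 SE, Nqo1 by -0.70 ± 0.14 SE and Msra by -0.67 ± 0.14 SE, none past the test over all genes. The median was -0.09, or -0.18 without mutant 2 and -0.16 without mutant 3 (camera adjusted p = 0.00317, and adjusted p = 0.41 with an estimated correlation). Among ROS-producing oxidases, 0 of 16 genes passed, while adjusted over the list alone 5 rose and 2 fell. The monoamine oxidase genes Maoa and Maob differed by -0.67 ± 0.13 SE and -1.14 ± 0.27 SE, and the NADPH oxidase subunit genes Cyba and Ncf1 by 0.56 ± 0.16 SE and 0.34 ± 0.09 SE. The median was 0.10 and the list did not pass (camera adjusted p = 0.17, and adjusted p = 0.536 with an estimated correlation), except without control 1 (median 0.18, adjusted p = 0.0488). Oxidative phosphorylation had 0 of 34 genes past the test and 0 adjusted over the list alone, yet 33 members lay below the control mean. Its median was -0.14 (camera adjusted p = 7.52e-05, and adjusted p = 0.527 with an estimated correlation), with Ndufa4 at -0.43 ± 0.13 SE and Uqcrq at -0.32 ± 0.12 SE.

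Interferon response and MHC class II genes had the highest median of all tested lists, 0.89, or 0.52 without control 2, with 0 of 22 measured members past the test over all genes. Adjusted over the list alone 10 rose and 0 fell, and 21 members lay above the control mean (camera adjusted p = 3.32e-11, and adjusted p = 0.369 with an estimated correlation). Usp18 differed by 1.94 ± 0.39 SE, the guanylate-binding protein genes Gbp6 and Gbp3 by 1.70 ± 0.35 SE and 0.56 ± 0.12 SE, and Oas1a by 1.21 ± 0.32 SE. The mean of the list was 8.57 in control 1, near the 8.69 to 8.87 of the mutants, and 7.37 and 7.80 in the other controls. Markers of T cells and intraepithelial lymphocytes moved with it. None of 19 passed, 0 did so adjusted over the list alone, and the median was 0.62, or 0.31 without control 2 (camera adjusted p = 2.61e-07, and adjusted p = 0.369 with an estimated correlation). Itgae differed by 0.87 ± 0.21 SE and Ccl5 by 1.51 ± 0.49 SE, and the mean of these markers in control 1, 6.75, lay within the range of the mutants, 6.57 to 7.14. B and plasma cell markers had 0 of 15 genes past the test and 1, Sdc1, higher adjusted over the list alone, at 0.87 ± 0.17 SE. Their median was 0.31, or 0.53 without mutant 2 (camera adjusted p = 0.0011, and adjusted p = 0.484 with an estimated correlation), and without control 3 the call was lost (median 0.19, adjusted p = 0.067). For macrophages and other myeloid cells, 0 of 20 passed and 0 adjusted over the list alone, with Cd14 at 0.60 ± 0.19 SE, Lyz2 at -0.35 ± 0.11 SE and a median of 0.25, or 0.11 without mutant 2 (camera adjusted p = 3.83e-05, and adjusted p = 0.369 with an estimated correlation).

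Genes of the antimicrobial and inflammatory epithelial response included Retnlb as the 1 riser among 24 measured, with 0 lower and 23 not past, and adjusted over the list alone 5 rose and 1 fell. Reg3g, which encodes a bactericidal lectin, differed by 0.87 ± 0.20 SE, whereas Reg3a differed by -0.55 ± 0.13 SE. The median was 0.32, or 0.17 without mutant 3 (camera adjusted p = 3.27e-05, and adjusted p = 0.369 with an estimated correlation). The unfolded protein response had 0 of 22 genes past the test and 2 higher adjusted over the list alone, the endoplasmic reticulum chaperone gene Dnajb9 at 0.56 ± 0.13 SE and Asns at 0.58 ± 0.15 SE. Its median was 0.22, or 0.13 without mutant 3 (camera adjusted p = 0.000102, and adjusted p = 0.369 with an estimated correlation).

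Secretory cell markers lay higher in the mutants, with opposite changes among gut hormones. Enteroendocrine markers had 1 gene up, 2 down and 20 not past among 23 measured, and adjusted over the list alone 7 rose and 2 fell. The incretin gene Gip fell 3.72-fold (log2 change -1.89 ± 0.11 SE, adjusted p = 0.000998) and the neurotensin gene Nts 2.23-fold, while the ghrelin gene Ghrl rose 1.99-fold (adjusted p = 0.00756). The Nts call was lost without control 2 (adjusted p = 0.0506) and the Ghrl call without control 3 (adjusted p = 0.0593). The median was 0.17, or 0.11 without mutant 1 (camera adjusted p = 0.0106, and adjusted p = 0.369 with an estimated correlation), and without control 1 the call was lost (adjusted p = 0.0557). Among 14 tuft cell markers 1 rose, Avil at 0.92 ± 0.13 SE (lost when any array but mutant 3 was left out, adjusted p up to 0.112), 0 fell and 13 did not pass, with 4 higher and 0 lower adjusted over the list alone. Their median was 0.11, or 0.05 without control 1 and 0.18 without mutant 3 (camera adjusted p = 0.0106, and adjusted p = 0.41 with an estimated correlation), and without mutant 1 the call was lost (adjusted p = 0.121). Goblet cell markers had 0 of 16 past the test and 1, Creb3l1, higher adjusted over the list alone, at 0.69 ± 0.12 SE, with a median of 0.31, or 0.19 without mutant 3 (camera adjusted p = 1.82e-05, and adjusted p = 0.369 with an estimated correlation). Paneth cell markers had 0 of 8 past the test, and adjusted over the list alone 2 rose, Mmp7 and Nupr1, and 1 fell, Lyz1. Their median was 0.20 (camera adjusted p = 0.0365, and adjusted p = 0.369 with an estimated correlation). The Paneth call was lost without control 1 (adjusted p = 0.0557), mutant 2 (median 0.12, adjusted p = 0.0957) or mutant 3 (adjusted p = 0.0726), and also without probe sets ending in _x_at (adjusted p = 0.0532).

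Among markers of position along the gut, the ileal gene Fabp6 differed between controls. Bile acid uptake and FXR targets had 0 of 10 past the test, and adjusted over the list alone 1 rose, the bile acid exporter gene Slc51b, and 1 fell, Cyp27a1. Fabp6, the ileal bile acid binding protein gene, read 9.15, 6.67 and 3.37 in controls 1, 2 and 3 and between 9.57 and 10.03 in the mutants (log2 change 3.40 ± 1.19 SE, adjusted p = 0.299). Slc10a2, the ileal bile acid carrier gene, read 3.31, 2.93 and 3.26 in the same controls, below the median probe set, and 3.99, 4.40 and 6.98 in mutants 1, 2 and 3 (log2 change 1.96 ± 0.67 SE, adjusted p = 0.289). The list median was 0.37 (camera adjusted p = 0.0483, and adjusted p = 0.369 with an estimated correlation). That call was lost under quantile normalisation (adjusted p = 0.0553), median centring (adjusted p = 0.0507), and without control 2 (adjusted p = 0.0562), control 3 (median 0.21, adjusted p = 0.1) or mutant 2 (adjusted p = 0.0957). Of 10 markers of the duodenum or proximal end 1 fell, Gip, 0 rose and 9 did not pass, with 4 lower and 1 higher, Cck, adjusted over the list alone. The median was -0.23 (camera adjusted p = 0.00446, and adjusted p = 0.369 with an estimated correlation). Of 13 markers of the ileum or colon 1 fell, Car4, 0 rose and 12 did not pass, with 1 lower adjusted over the list alone. Their median was 0.02 and their mean 0.16, while camera's direction was down, not past the threshold (camera adjusted p = 0.443, and adjusted p = 0.628 with an estimated correlation).

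Transcription factors and crypt genes changed singly. Among 24 intestinal transcription factors 2 fell, Nr1i3 and Onecut2 (log2 change -0.93 ± 0.12 SE), 0 rose and 22 did not pass, with 4 higher and 3 lower adjusted over the list alone. Onecut2 was dim in both groups, as given above. The Onecut2 call was lost when any array but control 1 was left out (adjusted p up to 0.102) and with the mean of its probe sets (adjusted p = 0.188), and Nr1i3 was lost without 4 of the arrays in turn, as given above. With the replicate block both were lost (adjusted p = 0.0555 for Nr1i3 and 0.0561 for Onecut2). The median was 0.07, the mean -0.03 and camera's direction up (camera adjusted p = 0.788, and adjusted p = 0.838 with an estimated correlation). Of 23 Wnt targets and stem cell markers 1 fell, the Wnt target Sp5 at -0.89 ± 0.12 SE (lost when any array but mutant 1 was left out, adjusted p up to 0.116), 0 rose and 22 did not pass, with 2 higher and 1 lower adjusted over the list alone, among them Prom1 at 0.61 ± 0.11 SE. The median was 0.08 (camera adjusted p = 0.121, and adjusted p = 0.369 with an estimated correlation). Proliferation genes had 0 of 30 past the test and 0 adjusted over the list alone, with Tk1 at -0.69 ± 0.22 SE and a median of -0.12 (camera adjusted p = 0.0297, and adjusted p = 0.628 with an estimated correlation). The proliferation call was lost without control 1 (adjusted p = 0.231), control 3 (median -0.05, adjusted p = 0.381), mutant 1 (median -0.07, adjusted p = 0.101) or mutant 3 (adjusted p = 0.116), and the median was -0.22 without control 2 and -0.19 without mutant 2. p53 targets and cell death had 0 of 15 past the test and 0 adjusted over the list alone, a median of 0.05 and a camera adjusted p of 0.396 (adjusted p = 0.672 with an estimated correlation), which became 0.0385 without mutant 1 (median 0.13). Tight junction and adhesion genes had 0 of 24 past the test, and adjusted over the list alone 2 rose, Cldn23 and Cldn4, and 1 fell, Cldn15. Cldn4 differed by 1.12 ± 0.24 SE and Cldn15 by -0.72 ± 0.12 SE, and the median was 0.04 (camera adjusted p = 0.217, and adjusted p = 0.628 with an estimated correlation). Circadian clock genes went both ways, with 0 of 18 past the test and 3 higher and 4 lower adjusted over the list alone. Nr1d2 differed by -0.94 ± 0.16 SE and Tef by -1.22 ± 0.26 SE, against 0.51 ± 0.13 SE for Bhlhe40, and the median was -0.17 (camera adjusted p = 0.415, and adjusted p = 0.653 with an estimated correlation).

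Markers of the remaining tissue layers showed no gene past the test over all genes. Smooth muscle had 0 of 16 adjusted over the list alone and a median of 0.04 (camera adjusted p = 0.326, and adjusted p = 0.775 with an estimated correlation), with camera adjusted p of 0.0102 without control 3 (median 0.16) and 0.0337 without mutant 3 (median 0.10), and medians of -0.03 without control 1 and -0.02 without mutant 2. Fibroblasts and matrix had 1 of 18 higher, Pdgfrb at 0.74 ± 0.15 SE, and 1 lower, Fbln1 at -0.93 ± 0.21 SE, adjusted over the list alone. Their median was 0.12 (camera adjusted p = 0.069, and adjusted p = 0.587 with an estimated correlation), and camera adjusted p was 0.0221 without control 2, 0.0215 without control 3 and 0.00216 without mutant 3 (median 0.23), against medians of 0.03 without control 1 and 0.01 without mutant 2. Endothelium had 0 of 14 adjusted over the list alone and a median of 0.04 (camera adjusted p = 0.452, and adjusted p = 0.82 with an estimated correlation), with 0.0379 as camera adjusted p without control 2 (median 0.09), and a median between -0.05 and 0.12 with 1 array left out. Enteric neurons and glia had 0 of 14 adjusted over the list alone, a median of 0.01 and a mean of -0.0055 with camera's direction up (camera adjusted p = 0.855, and adjusted p = 0.9 with an estimated correlation). Fat had 0 of 9 adjusted over the list alone and a median of 0.42 (camera adjusted p = 0.296, and adjusted p = 0.641 with an estimated correlation), and 0.0337 as camera adjusted p without mutant 3 (median 0.64), while the median was -0.17 without mutant 2. Red blood cells had 3 measured markers, too few for the set test, with 0 adjusted over the list alone and a median of 0.19. Pancreatic acinar cells had 0 of 14 adjusted over the list alone and a median of -0.89 (camera adjusted p = 0.0318, and adjusted p = 0.628 with an estimated correlation). Without control 3, the array that held these transcripts, the acinar median was 0.06 and the call was lost (adjusted p = 0.365), and it was lost too without mutant 1 (adjusted p = 0.062), mutant 2 (adjusted p = 0.0957) or mutant 3 (adjusted p = 0.0747).

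**Figure D3:**
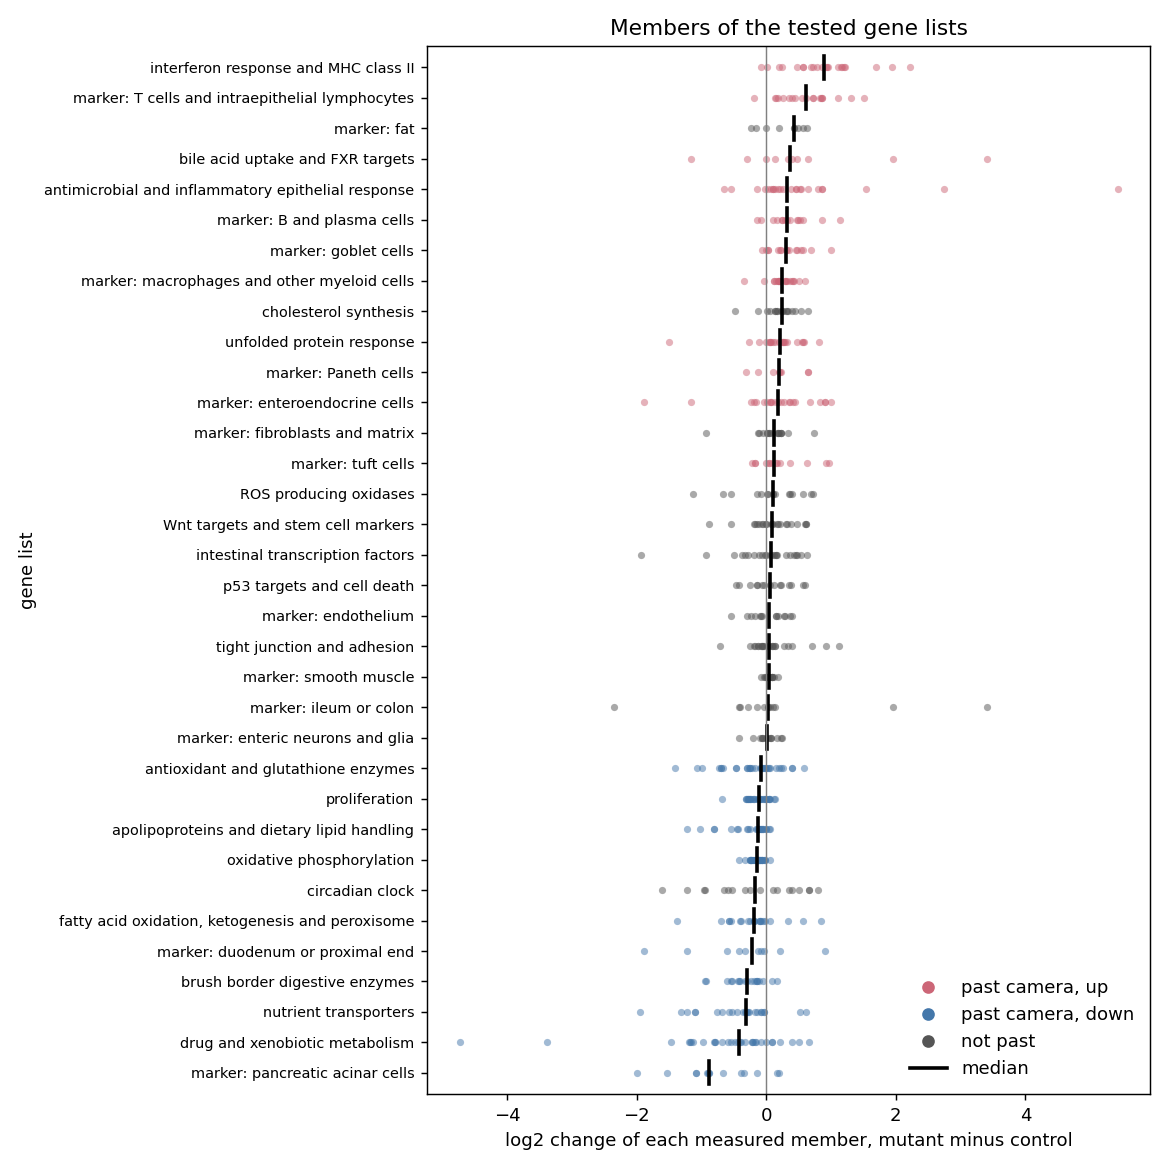
Log2 change of each measured member, mutant minus control (horizontal axis), for the 34 tested gene lists (vertical axis), with the median as a black bar and colour giving camera's call at the preset correlation. Medians run from -0.89 for pancreatic acinar markers, which rest on control 3, to 0.89 for the interferon response and MHC class II, and 11 lists passed upward and 10 downward.

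By camera at the preset correlation 21 of 34 lists passed, 11 upward and 10 downward. Splits of the arrays that mixed controls with mutants passed from 6 to 17 lists in the same test. Part of the group difference remains in such splits, so these counts are not a rate of false calls. With an estimated correlation 0 passed, where the smallest adjusted p was 0.369 and 1 list had an unadjusted p under 0.05, and limma's fry also passed 0. With a floor at the 20th percentile, with no moderation of the variance, and without control 3 and mutant 2 together, the bile acid, proliferation, Paneth and acinar calls were lost (adjusted p from 0.0574 to 0.104, from 0.0781 to 0.137 and from 0.124 to 0.25). The bile acid call was lost too with the Y-linked covariate (adjusted p = 0.058) and over probe sets above the median level (adjusted p = 0.0781), as was the Paneth call with that covariate (adjusted p = 0.0545). Fibroblasts and matrix passed with the mean of a gene's probe sets (adjusted p = 0.0468) and the replicate block (adjusted p = 0.0437).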

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

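The tests of co-movement of the interferon genes and of an effect of the mutation on the clock were chosen only after the result was seen.

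Outside the comparison of named genes, 10092 probe sets had several gene symbols or none listed. Of these, 2 were higher and 3 lower in mutants at an adjusted p under 0.05 over all probe sets. With every probe set tested on its own, 87 of 45037 were called. Both higher probe sets had several symbols and differed by 0.92 ± 0.10 SE and 2.11 ± 0.28 SE on the log2 scale. The 3 lower ones had no listed symbol and differed by between -2.86 and -1.21. The largest fall ended at a mutant mean of 3.03, below the median probe set, so its size is uncertain. No explanation was tested for these calls.

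The interferon response and MHC class II genes lay 0.887 higher (log2, mean of the list) in the mutants than in the controls, and T cell markers lay 0.613 higher, with medians of 0.52 and 0.31 without control 2. With the T cell marker mean as a covariate the difference was 0.287, with a 95% interval from -0.445 to 1.02, so neither a greater share of lymphocytes in the biopsy nor an added change within the epithelium was excluded. Of the 19 T cell markers, 1 stood on another list, and the 6 arrays are too few to part both. The genes of the list also moved together between animals, and camera's adjusted p with an estimated correlation was 0.369, so the difference may come from which animals were drawn. Both explanations stay open beside an effect of the mutation. They need not exclude it, as these arrays cannot tell whether a greater share of lymphocytes would itself follow from the mutation.

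The list of 18 clock genes did not pass camera. The 8 placed in the phase of Dbp lay lower in the mutants (median -0.79) and the 5 placed in that of Arntl higher (median 0.39). Of the other 5, Bhlhe40, Per1 and Tsc22d3 lay higher and Cry2 and Bhlhe41 lower. These phase groups were not part of the lists fixed beforehand, so the pattern depends on which genes were placed in each. Per1, which lay higher, was placed in neither, so the agreement within the groups is not evidence by itself. The mean of the Dbp group minus that of the Arntl group was 0.57, 0.27 and 0.87 in controls 1 to 3 and 0.07, -0.60 and -1.47 in mutants 1 to 3, so mutant 1 lay near control 2 and mutant 3 furthest away. The hour of tissue collection could give this, and it would also lower other outputs in phase with Dbp. Of these, Usp2 differed by -1.02, Wee1 by -0.09 and Lonrf3 by 0.07, with a mean of -0.348 and a 95% interval from -0.786 to 0.09, which leaves the hour of collection open. An effect of the mutation on the clock cannot be told apart from it, because no hour is given in the labels used here.

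Fabp6, an ileal gene, read 9.15, 6.67 and 3.37 in controls 1 to 3, which may reflect where along the gut each piece was taken. The ileal gene Slc10a2 stayed between 2.93 and 3.31 in them, below the median probe set, so it cannot rank these pieces. The mean of the proximal markers ran opposite to Fabp6, at 7.585, 7.764 and 7.852 in controls 1 to 3. It was 7.503, 7.473 and 7.138 in mutants 1 to 3, but that list holds Gip, which fell, so its mutant means do not measure position alone. If position made the changed genes, those called without control 1 would lie most of the way to the mutants in that array. Their median position was 0.245 of the way, with quartiles of 0.119 and 0.625 over 76 genes, against 0.0466 in control 2 over 24 genes and -0.0677 in control 3 over 22 genes. The median lay nearer to the other controls than to the mutants, while the upper quartile lay nearer to the mutants, so position stays open for part of these genes. Control 1 also had Y-linked transcripts and high interferon genes, so position is not the only way in which it differed.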

How the results depend on the processing

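The Y-linked covariate and the joint omission of control 3 and mutant 2 were chosen after the data were seen, and the other alternatives before. In all 96 changed genes the groups do not overlap, so leaving out arrays could not turn their direction, and no other refit turned a gene that it tested. Of the 35 named genes past the test, Cyp2b10 and Pm20d1 passed in each refit, and of 629 alternative values 421 passed. Counts of changed genes (higher, lower) were 2 (0, 2) with a floor at the 20th percentile and 2 (0, 2) with no moderation of the variance, Cyp2b10 and Pm20d1 in both. The moderated degrees of freedom were 8.06 in the main fit and 4.69 with the floor, and the test with no moderation has 4. Genes at the floor in every array have no spread, and whether this lowered the degrees of freedom was not tested. All values of the brightest Hnf4a probe set lay above the floor of 2.78, and its log2 change was -2.56 with and without it. For Hnf4a the floor therefore changed the test and not the signal. Array weights gave 150 (62 higher), the Y-linked covariate 194 (68, 126), an adjusted p under 0.01 gave 20 (5, 15) and a change of at least 2-fold 20 higher. Leaving out control 3 and mutant 2 together gave 4 (1, 3), with fewer samples. Leaving out 1 array gave from 22 to 96 changed, 7 to 45 higher and 15 to 51 lower. Hnf4a ran from -2.88 to -2.39 with 1 array left out, and missed the threshold with the floor (-2.56, adjusted p = 0.114), with no moderation (-2.56, adjusted p = 0.275) and with both arrays left out (-2.47, adjusted p = 0.205), over a range of adjusted p from 0.000132 to 0.275. Nothing in the labels says whether replicate numbers pair the animals. Same-numbered deviations correlated at 0.0725, 0.0685 and -0.0181, which cannot show that the animals were unpaired. The replicate block gave 62 genes (23, 39), 48 of them shared. Among the named genes, the block ended the calls of Abcc2, Avil, BC064078, Myl7, Nr1i3, Onecut2, S100g and 2210407C18Rik. It also ended those of Slc22a4, Slc5a6, Slc6a19, Sp5, St8sia6 and Sval1. The number of lists past camera was 0 with an estimated correlation and 0 with fry, and 13 lists passed in every other refit. The pancreatic acinar median reversed to 0.0633 without control 3 and to 0.084 without control 3 and mutant 2, and ran from -1.19 to 0.0633 with 1 array left out. Apart from the causes given, the cause was not tested. Signal close to background limits the dim genes. Of the 10 splits of the 6 arrays into 3 and 3, the real split alone (1 of 10) gave 96 genes and the highest other gave 0. For lists the real split gave 21 (again 1 of 10 as large), and the others gave from 6 to 17. Camera at the preset correlation therefore passed lists in every split, also where controls and mutants were mixed. Each mixed split has unequal numbers of controls and mutants on each side, so part of the group difference remains between its sides. The rest adds to the spread within them. The counts of lists and genes in mixed splits are therefore not rates of false calls. The 10 splits are also too few for a share under 0.05.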

Other observations

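The genes in this part were chosen after their values were seen, as were the gene families. Of the 96 changed genes, 80 were on none of the lists, 33 of them higher and 47 lower. Among the lower genes were the carnosine dipeptidase gene Cndp1 at -1.76 ± 0.25 SE, the agmatinase gene Agmat at -1.73 ± 0.22 SE, Upb1 of pyrimidine and beta-alanine metabolism at -1.18 ± 0.15 SE and Cth, which makes cysteine, at -0.90 ± 0.13 SE. Also lower were the cation exporter gene Slc47a1 at -1.47 ± 0.20 SE, Cyp2c68 at -1.36 ± 0.12 SE, Cyp2d22 at -1.18 ± 0.12 SE and Ugdh, which makes the glucuronic acid donor, at -0.68 ± 0.11 SE. In the Akr1c family 2 of 8 measured genes fell and 7 lay below the control mean, and in the Cyp2c family 1 of 11 fell and 9 lay below it. The members below it include Akr1c18, Akr1c20, Akr1c21, Cyp2c29, Cyp2c39, Cyp2c50 and Cyp2c70. These read below the median probe set in both groups, so the counts alone do not show a fall of either family. The brighter Akr1c genes all lay lower in the mutants. Besides the 2 that fell, Akr1c12 differed by -1.05 ± 0.22 SE and Akr1c13 by -1.18 ± 0.23 SE. Neither passed limma's test over all genes (adjusted p = 0.0959 and 0.0839). Among brighter Cyp2c genes, Cyp2c55 differed by -0.08 ± 0.17 SE and Cyp2c65 by 0.50 ± 0.13 SE. Of the changed genes named in this part, Cyp2c68 alone passed with any 1 array left out, and adjusted p of the others reached from 0.0505 for Cyp2d22 to 0.258 for Slfn2.

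Among zinc transporter genes 2 fell and 1 rose, and the family median was -0.0045. Slc30a2 fell by 1.22 ± 0.14 SE and Slc39a5 by 0.95 ± 0.15 SE, Slc39a8 rose by 0.77 ± 0.11 SE, and the other 21 of 24 measured members of these families did not pass. Mt1 was the 1 metallothionein of 4 that rose, and Mt2 differed by -0.45 ± 0.51 SE. Also higher were the interleukin-7 receptor gene Il7r at 0.61 ± 0.10 SE, Fermt3 at 0.88 ± 0.13 SE, Slfn2 at 0.75 ± 0.12 SE, Crlf2 at 0.81 ± 0.10 SE and the interferon-induced Gbp7 at 0.98 ± 0.12 SE, in arrays whose T cell markers lay 0.613 higher in mutants. Gng13, a taste and tuft cell G protein gene, rose by 1.26 ± 0.19 SE and the growth factor gene Bmp2 by 0.95 ± 0.12 SE. Of the control values of Gng13, 2 of 3 lay below the median probe set of their array, so the size of its change is uncertain. Hnf4g, the paralog of Hnf4a, differed by 0.16, with a 95% interval from -0.194 to 0.521 and an adjusted p of 0.756 by limma. A change of either sign within that interval therefore remains possible in these 6 arrays. In them Hnf4a missed the threshold with a floor (adjusted p = 0.114 by limma), at an unchanged log2 change of -2.56.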
